A study of Mus musculus with 247 samples.

How the data were processed

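The series holds 247 samples of the mouse macrophage line RAW264.7. Tables of values cover 46 of them: 16 RNA-seq, 6 ATAC-seq and 24 ChIP-seq libraries (8 for PU.1, 8 for JunB, 4 for MED1 and 4 for RNA polymerase II). The other samples, among them all GRO-seq and 4C-seq samples, were not analysed here. Groups were taken from the labels: genotype (WT or GPS2 KO, made by CRISPR) and treatment (none, or LPS for 6 hours at 10 ng/ml in RNA-seq and for 2 hours in ChIP-seq). ATAC-seq cells were untreated. ChIP-seq chromatin was crosslinked with DSG and formaldehyde.

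The authors deposited RNA-seq and ChIP-seq values as reads per 10000000 mapped reads, written with decimal commas. In every such column the low values were whole multiples of the value of 1 read, to within 0.05 of a read and tested up to 200 reads, so whole reads could be recovered. The headers and labels call these values counts, which they are not. A test for counts was possible on the recovered reads and was not run. The authors deposited ATAC-seq values on a log2 scale, after a transformation in their differential step; columns had nearly equal medians and no whole-read steps. The exact transformation was not stated, so an ATAC-seq change of 1 is a change of 1 on that scale. The deposited tables also hold the authors' log2 fold changes and adjusted p-values (FDR) for 12 comparisons, which were set beside the tests made here and used for nothing else. Per the file headers and labels, the authors used HOMER tables on merged peaks (MACS2 for ATAC-seq) or RefSeq transcripts, build mm9, with Bowtie2, BWA, HISAT2, DESeq2 and edgeR named but without versions. The command behind the JunB table was not stated. In the MED1 and RNA polymerase II tables the authors' group means had been rescaled so that the peaks of each library sum to 10000000. Another 8 columns held rescaled copies of values and were not used. For RNA, 22 gene symbols turned into dates were read from the annotation column.

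Values were analysed in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Overlaps of peaks were found with bedtools 2.31.1. RNA-seq and ChIP-seq values were divided by a trimmed mean of M values factor computed on the recovered reads of all features, a pseudocount of 1 was added and log2 was taken. A feature was tested if it reached 10 reads at the median depth in as many libraries as the smallest group and 15 reads in all. This left 11791 of 14378 genes, 52009 of 52093 PU.1, 58810 of 58888 JunB, 26052 of 26718 MED1 and 23081 of 23360 RNA polymerase II sites, and all 73206 ATAC-seq sites were tested. The RNA and ATAC-seq tests were limma with a trend of the spread on the mean and robust moderation, with all libraries of an assay in 1 fit and 1 coefficient per group. The ChIP-seq tests were limma with precision weights, estimated on the recovered reads. All tests are two-sided, with Benjamini-Hochberg adjusted p under 0.05 within each comparison.

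The comparisons, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The planned test, edgeR's quasi-likelihood test on counts, was not run, since the values are not counts, and it was not run on the recovered reads either. The tests used were therefore chosen with the data at hand. For ChIP-seq, limma without weights was tried first, along with other weighted fits and fits of only the groups compared, and the counts of called sites had been seen before the weighted fit was chosen. The reason for the choice was simulated data with the depth and levels of each table, in which 200 features with a mean over 50 reads changed 2-fold and the dispersion was 0.01 for RNA-seq and 0.005 for ChIP-seq. There, the unweighted fit gave p under 0.05 to 11.9% (without LPS) and 0.284% (with LPS) of unchanged JunB sites, against 5.17% and 4.9% with weights. With LPS it recovered 15 of 200 changed JunB sites, against 195 with weights. The weighted fit recovered 25 of 200 for the difference of the JunB LPS responses, 65 for JunB without LPS and 74 for the difference of the PU.1 responses. In the other comparisons it recovered 156 or more, and the RNA test 198 or more. The test of ATAC-seq recovered 171 of 200 sites changed by 0.5.

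Gene lists (20, of which 19 had at least 2 tested members in RNA) were tested with limma's camera with a preset correlation of 0.01, and again with an estimated correlation and with fry. Adjusted p for lists runs over all lists and comparisons of RNA, and over all lists within each ChIP-seq or ATAC-seq table. Sites belong to the nearest gene as the deposited tables annotate it. The change at the sites of genes called higher and lower in RNA was compared as a difference of medians, with 100000 permutations of the gene labels. A promoter site lies within 1 kb of a transcription start. Motifs were searched within 100 bp on each side of the site centre in the NCBIM37 mouse assembly, whose coordinates are those of mm9, and used for nothing else. Shares with a motif carry 95% Wilson intervals over sites, which cover counting error only, since sites are not independent replicates. The depth of each ATAC-seq and ChIP-seq library is the number of mapped reads that the file headers give. For RNA-seq the depth was recovered from the value of 1 read. The trend of the RNA values on transcript length used the lengths in the table.

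The rule for named genes took the corepressor genes and Ccl2 in each RNA comparison, the 6 genes with the largest change in each direction among those called, with a mean of at least 100 reads per 10000000 in the higher group and no overlap between groups, and the 3 members of smallest p of each list that passed or had at least 25% of its members called. For each comparison of sites it took the 5 with the largest change in each direction among called sites of at least median height, the site of smallest p of 10 genes fixed in advance, and all sites within 100 kb of Ccl2. The rule named 727 genes and sites. The text names 174 of them, a choice made after their values had been seen. Some genes the rule gives, and the counts of the corepressor list, are not reported here.

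Alternatives changed 1 choice at a time, except that the stricter threshold asks for adjusted p under 0.01 and a log2 change of at least 1 together: scaling (library totals, median of ratios, tags in peaks), filters, pseudocount (0.25 and 5), only the groups compared, a test against a log2 change of 1, site class, a stricter threshold, the replicate number as a term, weights, and each library left out in turn. Leaving out 1 of 2 ChIP-seq libraries leaves a lone library, which is assumed to vary like the other groups. An outlying value within a group of 4 was judged by Dixon's ratio. The LPS response within the RNA polymerase II and MED1 libraries was judged without untreated libraries of these targets. Genes whose RNA rose by at least 2 (log2) in both genotypes were compared with genes that changed by at most 0.5. This was done within deciles of untreated RNA, with 2000 bootstrap draws. Chance splits of the libraries used all 35 splits of 8 RNA libraries, all 10 of the 6 ATAC-seq libraries, and 100 drawn regroupings for the difference of the LPS responses. ChIP-seq groups hold too few libraries for such a count.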

Results

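The series covers 247 samples of RAW264.7, a mouse macrophage cell line, studied with and without lipopolysaccharide (LPS), the bacterial cell wall component that activates macrophages. Its labels count 131 ChIP-seq, 78 4C-seq, 16 GRO-seq, 16 RNA-seq and 6 ATAC-seq samples. The study asks how GPS2, a subunit of a nuclear corepressor complex, acts at enhancers during inflammatory activation. Values for 46 samples stand in 6 tables, and the other samples were not analysed here. These 46 are poly(A) RNA-seq of wild-type (WT) and GPS2 knockout (KO) cells, untreated or after 6 hours with LPS (4 libraries per group), ATAC-seq of untreated control and KO cells (3 per group), and ChIP-seq after 2 hours with LPS of the macrophage factor PU.1 and the AP-1 subunit JunB (2 per group, with untreated groups), the Mediator subunit MED1 and RNA polymerase II (2 per group, LPS only).

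Mapped reads ran from 12094940 to 22968591 per RNA-seq library and from 4038814 to 7108592 per ATAC-seq library. For ChIP-seq they ran from 8096466 to 10389811 for PU.1, from 8649049 to 16006472 for JunB, from 9793462 to 11932305 for MED1 and from 10230448 to 11113625 for RNA polymerase II. RNA means below are normalised reads per 10000000 mapped reads with their SD (n = 4 libraries), and log2 changes carry their SE. The 2 ChIP-seq libraries of each group agreed within sampling noise, with a chi-square per peak between 0.823 and 1.16, and are therefore counted as 1 sample. ChIP-seq means thus stand without an SD, and ChIP-seq tests compare the libraries, not independently grown cells. On the same measure, per gene, RNA-seq pairs ran from 1.24 to 138.4, and those of KO cells with LPS from 1.24 to 1.85. The RNA SDs of KO cells with LPS thus lie close to sampling noise. They may understate the spread between independently grown cells. No label names separate clones of the KO cells, so a difference between clones cannot be told from the loss of GPS2. Coordinates are those of mouse build mm9.

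Gps2 RNA (NM_019726, chromosome 11, 69727522 to 69730096) fell in the KO cells but did not vanish. It averaged 434 ± 18.5 in WT and 132 ± 2.38 in KO cells without LPS, and 440.5 ± 36.7 and 90.3 ± 9.60 with LPS. The log2 changes were -1.70 ± 0.08 (adjusted p = 8.59e-11) and -2.28 ± 0.08 (adjusted p = 5.41e-12). LPS lowered it in KO cells by -0.55 ± 0.08 (-0.94 with library totals), and the LPS responses of KO and WT cells differed by -0.57 ± 0.11. Ccl2 (NM_011333, chromosome 11, 81849079 to 81850954), which encodes a monocyte-attracting chemokine, moved the other way. It rose from 87.2 ± 6.12 in WT to 188 ± 19.7 in KO cells without LPS (log2 1.1001 ± 0.16, adjusted p = 5.94e-05), and from 26980 ± 9663 to 41120 ± 1582 with LPS (log2 0.67 ± 0.16, adjusted p = 0.00345). Replicate 4 of WT with LPS stood at 41300 for Ccl2 against 20930 to 24290 in replicates 1 to 3. Without it the change with LPS was 0.90.

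**Figure D1:**
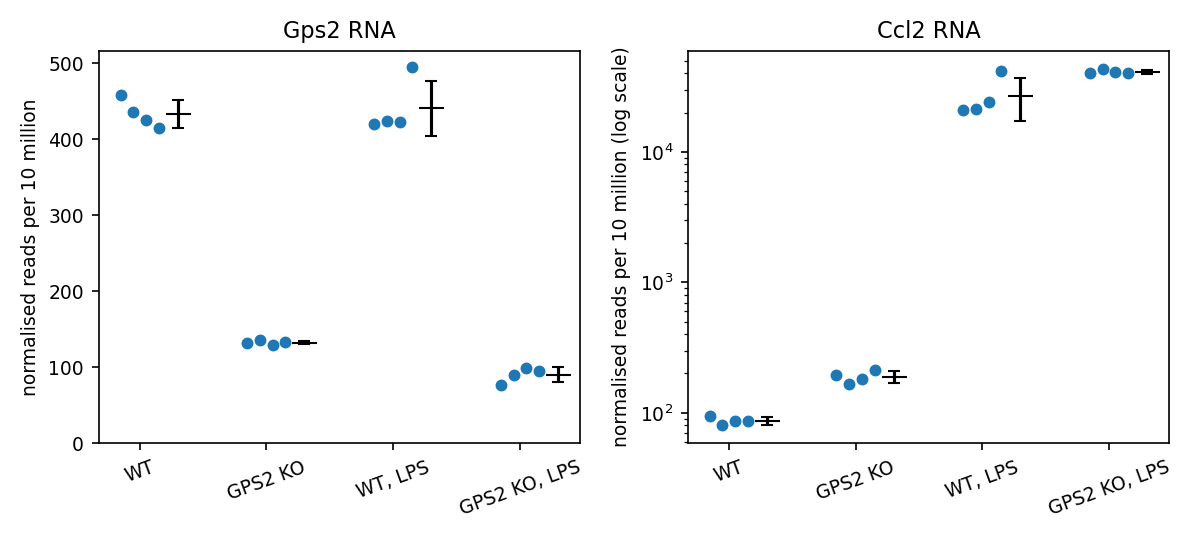
Gps2 and Ccl2 RNA in each of the 16 libraries (points), in normalised reads per 10000000 mapped reads, with the mean and SD of each group of 4 (bars); the Ccl2 axis is logarithmic. Gps2 averaged 132 in untreated KO and 434 in untreated WT libraries, and Ccl2 averaged 188 and 87.2.

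Without LPS, the KO cells held more RNA of the integrated stress response and of inflammatory mediators. Gpnmb, a lysosomal glycoprotein of macrophages, rose from 2129 ± 71.1 to 39170 ± 846 (log2 4.20 ± 0.09). Slpi, a secreted protease inhibitor, rose from 5.45 ± 0.934 to 172 ± 14.8, and Fabp4, a fatty acid carrier, from 9.80 ± 0.196 to 222 ± 8.62. The receptor genes Cd200r4 and Trem3 rose from 3.25 ± 1.44 to 161 ± 8.66 and from 5.66 ± 1.33 to 141 ± 8.41, and Tmem154 from 10.2 ± 3.39 to 379 ± 2.27. Cd36, a scavenger receptor, fell from 2104 ± 103 to 104 ± 15.0 (log2 -4.33 ± 0.11), Epop from 237 ± 9.80 to 15.9 ± 4.10 and the transcription factor gene Klf9 from 199 ± 8.08 to 21.9 ± 1.67. Zfp395 and Gypc averaged 112.5 ± 3.64 and 122 ± 6.36 in WT, and 0.240 ± 0.480 and 1.07 ± 0.482 in KO cells. Of 11791 genes tested, 2122 were higher and 2058 lower. Without replicate 4 of WT with LPS, which shares the estimate of the spread, 6993 genes passed, with 3462 higher and 3531 lower.

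Every tested member of the integrated stress response list, 15 of 15, was higher without LPS (15 adjusted over the list alone; median log2 1.18, camera adjusted p = 1.15e-13). Among them were Trib3 (97.9 ± 9.75 to 829.7 ± 36.7), the cystine transporter gene Slc7a11 (144 ± 17.4 to 1244 ± 25.99) and Asns, asparagine synthetase (1409 ± 13.2 to 3690 ± 84.8). Of 24 inflammatory cytokines and mediators, 15 were higher and 1 lower (16 and 1 adjusted over the list alone; 15 and 2 without replicate 4 of WT with LPS; adjusted p = 7.84e-06). Il1a rose from 14.04 ± 4.52 to 91.4 ± 23.4, Il1rn, the interleukin receptor antagonist, from 381.5 ± 17.2 to 1745 ± 75.6 and Tnf from 375 ± 23.2 to 708 ± 21.8. Of 18 lysosome and phagocytosis genes, 11 were higher and 2 lower (12 and 2 adjusted over the list alone; adjusted p = 0.000242, or 0.0874 with an estimated correlation). The protease genes Ctsb and Ctsd rose from 19190 ± 483 to 42180 ± 667 and from 10670 ± 218 to 26540 ± 637.

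Other lists tested lower without LPS. Of 19 cholesterol biosynthesis genes, 8 were lower and 1 higher (10 and 1 adjusted over the list alone; 14 and 1 without replicate 4 of WT with LPS; adjusted p = 0.00378, or 0.135 with an estimated correlation), among them Insig1 (785 ± 38.3 to 415 ± 14.8) and the sterol carrier gene Stard4 (827 ± 54.0 to 519 ± 30.5). Of 18 glycolysis and hypoxia genes, 10 were lower and 3 higher (11 and 3 adjusted over the list alone; adjusted p = 0.0339, or 0.116 with an estimated correlation), among them Pfkl (3076 ± 96.8 to 1722 ± 33.6) and the lactate exporter gene Slc16a3 (4480 ± 224 to 2587 ± 216). Of 5 alternative activation genes, 4 were lower (4 adjusted over the list alone; adjusted p = 0.0206, or 0.0947 with an estimated correlation), and Egr2 went from 48.5 ± 6.58 to 19.6 ± 2.28.

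Among 16 chemokines 7 were higher and 4 lower (8 and 4 adjusted over the list alone; adjusted p = 0.53): Ccl3 rose from 1121 ± 41.1 to 3773 ± 109.8 and Cxcl16 fell from 776 ± 41.4 to 128 ± 11.3. Among 12 AP-1 and related factors 4 were higher and 6 lower (4 and 6 adjusted over the list alone; adjusted p = 0.628): Jun rose from 388 ± 11.2 to 899 ± 9.99 and Fos fell from 439 ± 7.54 to 132.5 ± 6.94. Among 22 macrophage identity genes 10 were higher and 5 lower (10 and 5 adjusted over the list alone; adjusted p = 0.142): Maf rose from 14.7 ± 0.929 to 69.3 ± 4.30 and Cd36 fell from 2104 ± 103 to 104 ± 15.0. Abca1, the cholesterol efflux pump of the LXR list (3 higher and 7 lower of 15, 3 and 8 adjusted over the list alone, adjusted p = 0.0901), rose from 43.1 ± 2.499 to 185 ± 20.4. The granulocyte and dendritic cell markers had 3 of 4 tested members higher (3 adjusted over the list alone; adjusted p = 0.0473, or 0.113 with an estimated correlation), of which Csf3r rose from 16.6 ± 1.69 to 94.5 ± 5.42.

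**Figure D2:**
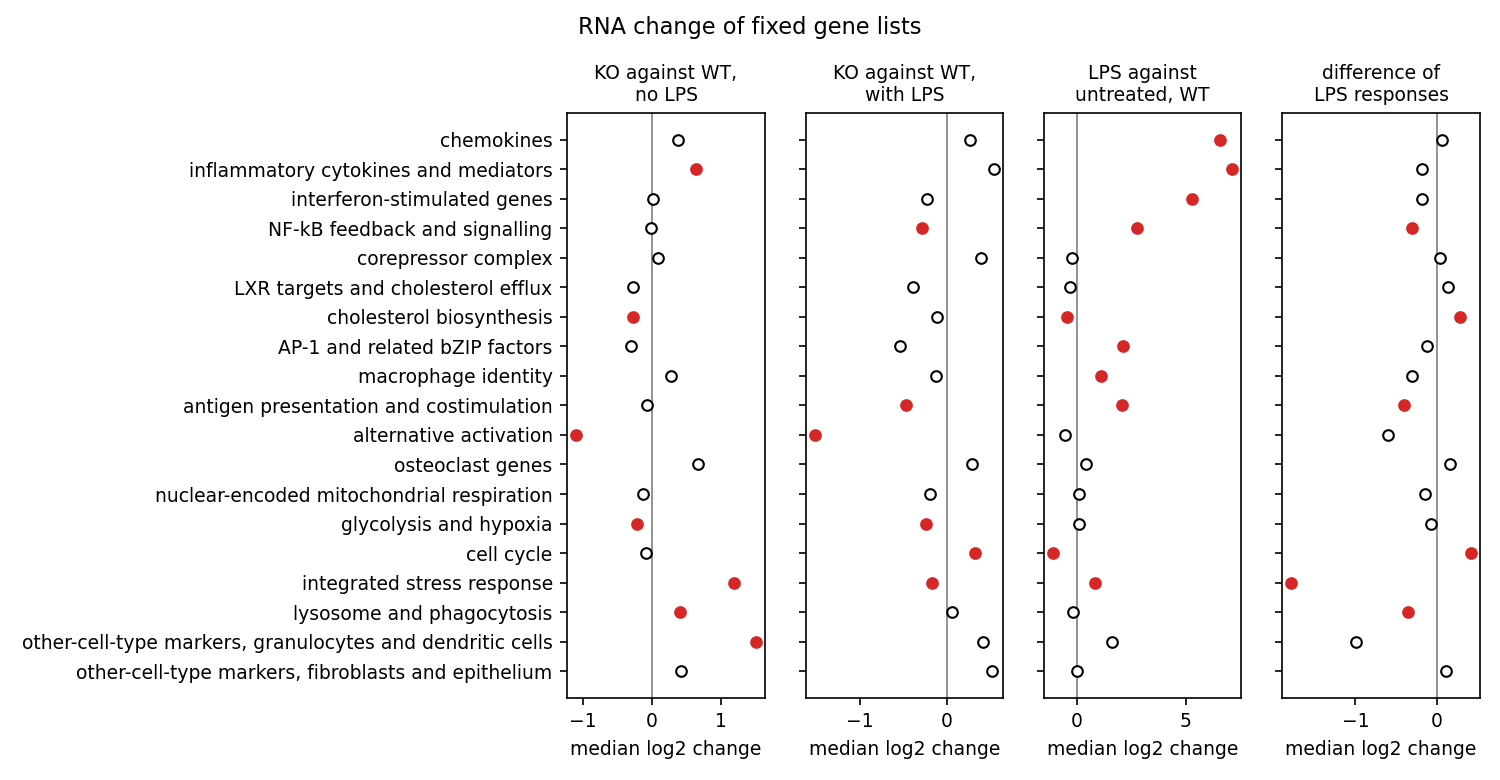
Median log2 change in RNA of each fixed gene list (horizontal axis, log2) in 4 comparisons (panels); filled red points mark lists with a camera adjusted p under 0.05 and open points the rest. The integrated stress response list lay at 1.18 without LPS and at -1.79 for the difference of the LPS responses.

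With LPS, the KO cells held more RNA of cell cycle genes and less of NF-kB feedback genes than WT cells with LPS. Pilra, a myeloid receptor, rose from 33.9 ± 4.99 to 541 ± 20.4, Sorl1 from 73.6 ± 19.5 to 896 ± 13.4 and Csf2, the granulocyte-macrophage growth factor, from 316 ± 127.5 to 3652 ± 111. Treml2 and Trem1 averaged 2.30 ± 1.08 and 10.4 ± 2.75 in WT and 219 ± 13.7 and 160.4 ± 12.9 in KO cells. Adgrl2 and Lpar1, receptor genes, averaged 157.5 ± 46.5 and 205 ± 7.996 in WT and 0.697 ± 0.960 and 1.68 ± 0.805 in KO cells. Scarf1 fell from 259 ± 25.9 to 11.1 ± 2.49, Gja1, a gap junction gene, from 437 ± 86.7 to 19.6 ± 4.33 and Shisa3 from 175 ± 17.7 to 7.05 ± 3.22. Gpnmb stayed far higher in KO cells (945 ± 151 against 11240 ± 62.2). In all, 2600 genes were higher and 2603 lower, or 3470 and 3385 without replicate 4 of WT with LPS. The changes went with transcript length by a rank correlation of 0.312, which was 0.0842 without that replicate. A fit of only the groups compared called 3132 genes. Both without and with LPS, 1099 genes were higher and 1225 lower in KO cells, where independent calls would give 467.9 and 454.3.

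The cytokines and mediators moved both ways with LPS: 13 of 24 were higher and 7 lower (13 and 7 adjusted over the list alone; 12 and 7 without replicate 4 of WT with LPS; adjusted p = 0.132). Tnf rose from 9472 ± 198 to 24930 ± 119.9, while Il10, an anti-inflammatory cytokine, fell from 1520 ± 427 to 272 ± 5.54. Of 22 NF-kB feedback and signalling genes, 12 were lower and 3 higher (12 and 5 adjusted over the list alone; 13 and 5 without replicate 4; adjusted p = 0.00362, or 0.0212 with an estimated correlation). Dusp1, a phosphatase that ends kinase signalling, fell from 5180 ± 112 to 1210 ± 10.1, Bcl3 from 3157 ± 23.3 to 1104 ± 51.8 and Nfkbie from 566 ± 7.00 to 215 ± 13.8. Of 26 cell cycle genes, 13 were higher (13 adjusted over the list alone; 16 higher and 1 lower without replicate 4; adjusted p = 3.78e-05, or 0.0024 with an estimated correlation), among them Ccnd1, cyclin D (2221 ± 168 to 7726 ± 102), Rrm2 (276 ± 21.8 to 589 ± 15.3) and Mcm4 (613 ± 33.6 to 1054 ± 22.1).

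All 5 alternative activation genes were lower with LPS (5 adjusted over the list alone; adjusted p = 0.000946, or 0.0263 with an estimated correlation), Klf4 from 117 ± 33.4 to 8.86 ± 4.14. Of 18 glycolysis and hypoxia genes, 11 were lower and 2 higher (12 and 2 adjusted over the list alone; 14 and 2 without replicate 4 of WT with LPS; adjusted p = 0.00256, or 0.0453 with an estimated correlation), among them the glucose transporter gene Slc2a1 (8335 ± 494 to 4735 ± 75.8) and Bnip3 (1272 ± 318 to 527 ± 31.2). Of 13 antigen presentation genes, 9 were lower and 1 higher (9 and 1 adjusted over the list alone). The camera adjusted p was 0.0365, or 0.465 with an estimated correlation. Tapbp fell from 12620 ± 617 to 7632 ± 142, and the costimulation gene Cd80 rose from 229 ± 34.6 to 788 ± 33.3. Of 15 integrated stress response genes, 8 were lower and 2 higher (8 and 2 adjusted over the list alone; 9 and 3 without replicate 4; adjusted p = 0.0321, or 0.164 with an estimated correlation), among them Chac1 (269 ± 21.1 to 107 ± 7.24) and Ddit4 (197 ± 32.9 to 52.0 ± 3.32).

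Further lists did not pass with LPS, though single members did. Among 16 chemokines 8 were higher and 7 lower (8 and 7 adjusted over the list alone; adjusted p = 0.928). Among 37 interferon-stimulated genes 9 were higher and 14 lower (9 and 15 adjusted over the list alone; adjusted p = 0.142). Ifnb1, interferon beta, rose from 73.5 ± 37.0 to 650.1 ± 28.96, and Irf1 fell from 1018 ± 36.2 to 503.5 ± 12.6. Among 22 macrophage identity genes 7 were higher and 11 lower (7 and 11 adjusted over the list alone; adjusted p = 0.301), and Csf1r rose from 4436 ± 897 to 11440 ± 175. Among 15 LXR and cholesterol efflux genes 2 were higher and 8 lower (2 and 8 adjusted over the list alone; adjusted p = 0.0734), and Abca1 fell from 766 ± 191 to 240.3 ± 24.1, opposite to its change without LPS. Among 10 osteoclast genes 4 were higher and 3 lower (5 and 3 adjusted over the list alone; 4 and 5 without replicate 4 of WT with LPS; adjusted p = 0.504), and Mmp9 rose from 976.5 ± 89.9 to 5189 ± 149. Of 25 respiration genes 2 were higher and 6 lower (0 and 5 adjusted over the list alone; 4 and 8 without replicate 4; adjusted p = 0.0809). Of 4 granulocyte and dendritic cell markers 2 were higher and of 2 fibroblast and epithelium markers 1 was higher (adjusted p = 0.508 for each); of 15 lymphocyte markers 4 stood in the table and 0 passed the filter on low values.

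Calls on partners of GPS2 in the corepressor complex were fragile. Without LPS, Tbl1xr1 went from 829.5 ± 69.4 to 1030 ± 18.3 (adjusted p = 0.0414). That call was lost without WT replicate 1 (adjusted p = 0.122), 2 (adjusted p = 0.0854) or 3 (adjusted p = 0.0666), KO replicate 1 (adjusted p = 0.0792), 2 (adjusted p = 0.0676), 3 (adjusted p = 0.0888) or 4 (adjusted p = 0.0764), WT with LPS replicate 3 (adjusted p = 0.0515), and KO with LPS replicate 1 (adjusted p = 0.0521), 2 (adjusted p = 0.0528), 3 (adjusted p = 0.0517) or 4 (adjusted p = 0.0525). Ncor1 averaged 1207 ± 134 in WT and 1583 ± 33.8 in KO cells (adjusted p = 0.273), Tbl1x 501 ± 47.3 and 577 ± 22.5 (adjusted p = 0.686) and Hdac3 727.5 ± 35.3 and 704 ± 21.4 (adjusted p = 0.749). Without replicate 4 of WT with LPS, Ncor1 (0.39, adjusted p = 0.00116) and Tbl1x (0.20, adjusted p = 0.0307) passed. Both also passed in a fit of only the groups compared (adjusted p = 1.92e-05 and 0.00312), and Ncor1 with library weights (adjusted p = 0.000429). The Tbl1xr1 change was 0.16 with the trend on transcript length removed (adjusted p = 0.0184). It did not pass without a trend of the spread on the mean (adjusted p = 0.0507).

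With LPS, Tbl1x went from 417 ± 209 to 705 ± 19.4 (log2 0.99, adjusted p = 0.029) and Tbl1xr1 from 594.5 ± 120.3 to 726 ± 23.5 (log2 0.31, adjusted p = 0.0361). Without replicate 4 of WT with LPS these changes were 0.47 and 0.175 and still passed. With library weights they were 0.45 and 0.16. With the trend on transcript length removed, that of Tbl1xr1 was only 0.05 and did not pass (adjusted p = 0.405). Without KO with LPS replicate 1, 2, 3 or 4, Tbl1x did not pass (adjusted p = 0.0536, 0.0543, 0.0604 and 0.0543), nor did Tbl1xr1 (adjusted p = 0.0812, 0.0708, 0.0523 and 0.0651). Tbl1xr1 also did not pass without WT with LPS replicate 3 (adjusted p = 0.0739). Ncor1 averaged 1198 ± 514 in WT and 1516 ± 76.1 in KO cells with LPS (adjusted p = 0.152), and Hdac3 719.0 ± 138 and 676 ± 25.8 (adjusted p = 0.554). With library totals Tbl1xr1 did not pass without (adjusted p = 0.179) or with LPS (adjusted p = 0.069), and in a fit of only the groups compared Tbl1x and Tbl1xr1 did not pass with LPS (adjusted p = 0.142 and 0.149).

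In WT cells, LPS raised cytokine and interferon genes and lowered cell cycle genes. All 16 chemokines, 24 cytokines and mediators, 37 interferon-stimulated genes and 22 NF-kB genes tested were higher (16, 24, 37 and 22 adjusted over the list alone), with camera adjusted p = 7.51e-12, 6.24e-16, 1.13e-22 and 2.18e-15. For the chemokines adjusted p = 0.0919 with an estimated correlation. Ccl2 rose by 8.20 ± 0.16 (log2), Ccl5 from 47.7 ± 4.01 to 20150 ± 5510, Cxcl10 from 107 ± 2.501 to 28600 ± 5086, Il1b from 117 ± 8.62 to 32950 ± 5074 and Rsad2, an antiviral gene, from 113 ± 5.87 to 34770 ± 2934. Il33, Il1a, Csf3 and Saa3 rose by 9.14 ± 0.30, 9.09 ± 0.20, 8.91 ± 0.21 and 8.80 ± 0.20, and Tnf by 4.66 ± 0.05. The feedback genes Zfp36 and Socs3 rose by 5.41 ± 0.05 and 7.27 ± 0.08, and Cd40 by 6.97 ± 0.13.

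LPS lowered 24 of 26 cell cycle genes and raised 1 in WT cells (24 and 1 adjusted over the list alone; adjusted p = 6.12e-08), Mcm7 from 1836 ± 42.9 to 431 ± 23.6. It lowered 15 of 19 cholesterol biosynthesis genes and raised 2 (15 and 2 adjusted over the list alone; adjusted p = 0.0018, or 0.116 with an estimated correlation), Dhcr7 from 809 ± 13.2 to 94.2 ± 12.8. The desaturase gene Scd2 fell from 15600 ± 708 to 1726 ± 286.5, Fam13c from 964 ± 48.5 to 29.5 ± 1.70 and St6gal1 from 312 ± 35.5 to 6.46 ± 2.35, while Ranbp3l went from 142 ± 6.61 to 1.29 ± 0.890. In all, 4027 genes were higher and 4270 lower. With library totals in place of the trimmed mean scaling, the median of all genes shifted by -0.46 and the counts became 1971 and 7046, so the direction of small changes with LPS rests on the scaling.

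In KO cells with LPS 37 of 37 interferon-stimulated genes, 22 of 22 NF-kB genes, 23 of 24 cytokines and mediators and 15 of 16 chemokines were higher (37, 22, 23 and 15 adjusted over the list alone). Of 26 cell cycle genes 22 were lower and 3 higher (22 and 3 adjusted over the list alone). Ccl2 rose by 7.77 ± 0.16 (log2) and Ccnd1 by 1.42 ± 0.05. Csf3 rose by 9.03 ± 0.21, Csf2 from 6.79 ± 1.88 to 3652 ± 111, Il6 from 7.90 ± 2.95 to 3760 ± 130.5 and the vasoconstrictor gene Edn1 from 6.09 ± 1.45 to 2921 ± 76.3. Of the 15 integrated stress response genes 11 were lower and 2 higher (12 and 2 adjusted over the list alone; adjusted p = 0.00378, or 0.0947 with an estimated correlation), Trib3 by -3.18 ± 0.08, Chac1 by -1.81 ± 0.08 and Psat1 by -1.04 ± 0.05. In WT cells 12 of these were higher and 2 lower (12 and 2 adjusted over the list alone; adjusted p = 0.0066, or 0.113 with an estimated correlation). In all, 3715 genes were higher and 4259 lower, or 1987 and 6780 with library totals (a shift of -0.38). Both genotypes shared 3091 genes higher and 3496 lower, where independent calls would give 1268.8 and 1542.4.

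The difference of the LPS responses, KO minus WT, was tested as its own term, so its sign does not give the size of a response. It was called negative for all 15 integrated stress response genes (15 adjusted over the list alone; median log2 -1.79, adjusted p = 2.91e-19), with -3.76 ± 0.11 for Trib3, -3.09 ± 0.12 for Chac1 and -1.56 ± 0.09 for Asns, as LPS raised 12 of them in WT cells and lowered 11 in KO cells. It was -3.81 ± 0.14 for Cth, a cysteine synthesis gene outside the list. Abca1 differed by -3.71 ± 0.22, Il7r by -3.46 ± 0.19, Saa3 by -3.01 ± 0.29, Il1rn by -2.58 ± 0.07 and Nos2, the inducible nitric oxide synthase gene, by -1.36 ± 0.18. Pilra and Cd36 differed the other way, by 2.49 ± 0.19 and 2.47 ± 0.16. The Ccl2 responses differed by -0.43 ± 0.23, which did not pass (adjusted p = 0.214). This difference takes in replicate 4 of WT with LPS, which stood at 41300 for Ccl2 against 20930 to 24290 in replicates 1 to 3. Removing the trend on transcript length gave -0.26 with adjusted p = 0.0487, so this call rests on that choice.

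The difference was called positive for 14 of 26 cell cycle genes (15 adjusted over the list alone; 21 without replicate 4 of WT with LPS; adjusted p = 3.64e-11), 2.32 ± 0.08 for Ccnd1 and 0.98 ± 0.08 for Rrm2. LPS lowered most of this list in both genotypes, by a median of -1.09 in WT and -0.74 in KO cells. The difference was called negative for 9 of 22 NF-kB genes and positive for 2 (13 and 2 adjusted over the list alone; 15 and 3 without replicate 4; adjusted p = 0.000885), -1.14 ± 0.11 for Dusp1 and -0.94 ± 0.08 for Nfkbie. It was called negative for 6 of 13 antigen presentation genes (8 adjusted over the list alone; 9 without replicate 4; adjusted p = 0.000127, or 0.174 with an estimated correlation), -2.56 ± 0.17 for Cd86, and for 10 of 18 lysosome genes with 1 positive (12 and 1 adjusted over the list alone; 13 and 3 without replicate 4; adjusted p = 0.000304, or 0.0874 with an estimated correlation), -0.77 ± 0.06 for Ctsb. Of 19 cholesterol biosynthesis genes, most of which LPS lowered in both genotypes, 6 had a positive and 1 a negative difference called (6 and 1 adjusted over the list alone; 10 and 1 without replicate 4; adjusted p = 0.0215, or 0.219 with an estimated correlation). In all, the difference was called positive for 1205 genes and negative for 1231. Without replicate 4 of WT with LPS, 4620 differed (2385 and 2235). The rank correlation of the difference with transcript length was 0.231, and -0.0575 without that replicate.

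Open chromatin was measured by ATAC-seq in untreated cells, as log2 values (mean ± SD, n = 3). The promoter of Spry2, a brake on growth factor signalling, closed in KO cells, from 7.07 ± 0.091 to 5.55 ± 0.119 at chromosome 14, 106295270 to 106298437 (adjusted p = 5.16e-48), and so did that of Efnb2, from 6.13 ± 0.067 to 4.72 ± 0.047 (chromosome 8, 8660884 to 8662074). Sites far from Adgrl3 (chromosome 5, 80458645 to 80460313) and near Fabp5 (chromosome 3, 10022333 to 10023206) opened, from 5.46 ± 0.046 to 6.72 ± 0.093 and from 5.50 ± 0.210 to 6.55 ± 0.016. The Tnf site (chromosome 17, 35337206 to 35339216) opened by 0.42 ± 0.07 (log2, adjusted p = 1.58e-06) and the Nos2 promoter (chromosome 11, 78733906 to 78734429) by 0.37 ± 0.07 (adjusted p = 0.000101). The Ccl2 promoter (chromosome 11, 81848682 to 81849527) differed by -0.20 ± 0.08, which did not pass (adjusted p = 0.0909). Of 73206 sites 2960 were more and 2311 less open. Without control replicate 1 the count was 3189 and without control replicate 3 it was 3345, and 13 passed adjusted p under 0.01 with a log2 change of at least 1.

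Grouped by nearest gene, 11 of 126 sites of cytokines and mediators were more and 3 less open (13 and 3 adjusted over the list alone; adjusted p = 0.0216, or 0.0857 with an estimated correlation), 9 of 127 sites of interferon-stimulated genes were more open (9 adjusted over the list alone; adjusted p = 0.0426, or 0.0925 with an estimated correlation) and 8 of 92 sites of integrated stress response genes were more open (8 adjusted over the list alone; adjusted p = 0.0126, or 0.0857 with an estimated correlation). Of 130 sites of glycolysis and hypoxia genes 11 were more and 2 less open (13 and 2 adjusted over the list alone, adjusted p = 0.0126, or 0.0857 with an estimated correlation), and 4 of 82 sites of alternative activation genes were less open (2 adjusted over the list alone, adjusted p = 0.0126, or 0.16 with an estimated correlation). In all, 29 of 220 list tests on peaks passed with the preset correlation. With an estimated correlation limma's camera called 0, and 34 had an unadjusted p under 0.05, while its fry test, which does not compare a list with other genes, called 72. For RNA, 20 of the 38 called list tests of 95 held with an estimated correlation.

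PU.1, the master regulator of macrophage genes, gained and lost single sites in KO cells. Without LPS, a site near Plpp3 (chromosome 4, 104941003 to 104941296) rose from 18.5 to 76.05 normalised tags and one near Adgrl3 (chromosome 5, 80223814 to 80224085) from 13.4 to 54.8, while one near Thsd4 (chromosome 9, 60369388 to 60369654) fell from 44.3 to 8.53. The site of smallest p for Ccl2 (chromosome 11, 81819377 to 81819644) averaged 46.7 and 62.4 tags, which did not pass (0.40 ± 0.16, adjusted p = 0.11). It passed without KO replicate 2 (0.63, adjusted p = 0.0338), and its change was -0.14 with library totals. A site near Abca1 (chromosome 4, 53211289 to 53211579) rose by 1.06 ± 0.26 (log2, adjusted p = 0.00181), or 0.54 with library totals (adjusted p = 0.0706). Of 52009 sites 2376 were higher and 1711 lower. The count was 1984 without WT replicate 1, 2537 without WT replicate 2, 1620 without KO replicate 1 and 1747 without KO replicate 2, and 1932 in a fit without precision weights. Library totals gave 273 higher and 24079 lower, with a shift of -0.53 in the median. In KO libraries 17.5% and 17.2% of tags lay in peaks against 24.8% and 25.2% in WT, so all changes are relative to the typical site.

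With LPS, another Plpp3 site (chromosome 4, 104978665 to 104979005) held 6.27 tags in WT and 54.2 in KO cells, and a Spred2 intron site (chromosome 11, 19855702 to 19855996) 60.5 and 11.1. The site of smallest p for Tnf (chromosome 17, 35337989 to 35338280) rose by 0.84 ± 0.24 (adjusted p = 0.0109), or 0.43 with library totals, which did not pass (adjusted p = 0.164). It was 0.50 without KO with LPS replicate 1 (adjusted p = 0.397), and did not pass without WT with LPS replicate 1 (adjusted p = 0.054) or replicate 2 (adjusted p = 0.165). The site of smallest p for Ccl2 (chromosome 11, 81824167 to 81824441) fell by -0.84 ± 0.23 (adjusted p = 0.00742), and did not pass without KO with LPS replicate 1 (adjusted p = 0.155) or WT with LPS replicate 1 (adjusted p = 0.0991). Of all sites 2578 were higher and 2020 lower, or 986 and 13166 with library totals (a shift of -0.40). The count was 2135 without WT with LPS replicate 1, 1777 without WT with LPS replicate 2, 2319 without KO with LPS replicate 1 and 2201 without KO with LPS replicate 2.

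In WT cells LPS raised PU.1 at a Txndc11 intron site (chromosome 16, 11144059 to 11144317) from 29.5 to 242 tags, near Pex2 (chromosome 3, 5860522 to 5860790) from 64.8 to 352 and at a Ccl2 site (chromosome 11, 81829577 to 81829840) from 12.9 to 41.2 (log2 1.66, or 1.00 with library totals), and lowered it in Stab2 (chromosome 10, 86391711 to 86391999) from 101 to 19.3. Of 67 chemokine sites 22 were higher and 1 lower (22 and 1 adjusted over the list alone; adjusted p = 2.81e-05, or 0.0839 with an estimated correlation). In all 5572 sites were higher and 4026 lower, or 689 and 30909 with library totals (a shift of -0.68). The count was 5635 without WT replicate 1, 5296 without WT with LPS replicate 1 and 4480 without WT with LPS replicate 2.

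The PU.1 responses to LPS differed between KO and WT, with a positive difference at 2238 sites and a negative one at 2065, among them Txndc11 with -2.19 ± 0.19. Library totals gave 3197 and 1122 (a shift of 0.14). The count was 2805 without KO replicate 1, 2802 without WT with LPS replicate 1, 2585 without WT with LPS replicate 2, 2771 without KO with LPS replicate 1 and 2667 without KO with LPS replicate 2. The Ccl2 site at 81824167 to 81824441 differed by -1.04 ± 0.32 (adjusted p = 0.0205). That call was lost with library totals (adjusted p = 0.0534), and without WT replicate 2 (adjusted p = 0.0804), KO replicate 2 (adjusted p = 0.122), WT with LPS replicate 1 (adjusted p = 0.095) or KO with LPS replicate 1 (adjusted p = 0.13).

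JunB sites gained in KO cells without LPS lay mostly at promoters: among those with a sequence, 2441 lay within 1 kb of a transcription start and 1059 farther away, where 1606 others were lost. In separate fits of the 2 classes 3199 sites were higher and 112 lower within 1 kb, and 643 and 911 farther away. Of the gained promoter sites 5.41% held the AP-1 motif, against 31.3% of the promoter sites not called. The Slpi promoter (chromosome 2, 164182297 to 164182636) rose from 3.13 to 24.2 tags (adjusted p = 0.00536), a call lost without WT replicate 2 (adjusted p = 0.072) and in a fit of only these groups (adjusted p = 0.0806). A site near Plpp3 (chromosome 4, 104920870 to 104921208) rose from 5.22 to 51.5, while one near Rprm (chromosome 2, 53593106 to 53593344) fell from 91.6 to 5.55. In untreated JunB libraries values were divided by 0.415 to 0.554, so normalised tags there exceed the deposited ones. Low untreated JunB values, such as those of WT at Slpi and Plpp3, thus rest on few reads. The Nos2 promoter (chromosome 11, 78733934 to 78734286) rose by 1.44 ± 0.36 (adjusted p = 0.00528), which did not pass without WT replicate 1 (adjusted p = 0.0816), WT replicate 2 (adjusted p = 0.0692) or KO replicate 1 (adjusted p = 0.0787). The Ccl2 site at 81837289 to 81837627 on chromosome 11 differed by 0.65 ± 0.24 (adjusted p = 0.0759), and passed without KO replicate 2 (0.94, adjusted p = 0.00778). Of 58810 sites 3508 were higher and 1651 lower. The count was 1237 without WT replicate 1 and 1027 without WT replicate 2, and library totals gave 1790 higher and 4755 lower (a shift of -0.25). A fit without precision weights, tried with the data at hand before the weighted fit was chosen, gave 4008 and 3321.

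With LPS, JunB at the same Plpp3 site stood at 6.20 tags in WT and 47.8 in KO cells, at a site near Olfm3 (chromosome 3, 114914750 to 114915088) at 4.77 and 45.1, and at one near Trim52 (chromosome 14, 106411256 to 106411530) at 53.7 and 12.97. JunB was lower at 41 of 179 sites of NF-kB genes and higher at 5 (41 and 5 adjusted over the list alone; adjusted p = 0.0211, or 0.166 with an estimated correlation), and lower at 23 of 73 sites of LXR genes and higher at 1 (24 and 1 adjusted over the list alone; adjusted p = 0.00328, or 0.17 with an estimated correlation). An Il1b site (chromosome 2, 129199037 to 129199475) rose by 0.43 ± 0.09 (adjusted p = 0.000209, and 0.28 with library totals) and a Nos2 intron site (chromosome 11, 78763966 to 78764151) by 0.99 ± 0.23 (adjusted p = 0.000751). The Ccl2 site at 81837289 fell by -0.33 ± 0.09 (adjusted p = 0.0022, 0.0685 without KO with LPS replicate 2). In all 7737 sites were higher and 8028 lower, or 6095 and 14820 with library totals (a shift of -0.14). The count was 10410 without WT with LPS replicate 1 and 9198 without KO with LPS replicate 2. A fit without precision weights called 13 higher and 3 lower, without the Il1b (adjusted p = 0.325), Nos2 (adjusted p = 0.294), Ccl2 (adjusted p = 0.577) and Trim52 (adjusted p = 0.073) sites.

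In WT cells LPS raised JunB in a Rab44 intron (chromosome 17, 29305987 to 29306155) from 4.18 to 56.5 tags and at the Il1b promoter (chromosome 2, 129196977 to 129197207) from 12.6 to 62.5, and lowered it near Atp2a3 (chromosome 11, 72767387 to 72767639) from 47.5 to 6.46. The Rab44 change of 4.23 ± 0.69 was 2.63 without WT replicate 1. Of 159 sites of cytokines and mediators 67 were higher and 13 lower (68 and 16 adjusted over the list alone; adjusted p = 7.54e-05, or 0.0928 with an estimated correlation). The Ccl2 site at 81837289 rose by 0.81 ± 0.17 (adjusted p = 0.000121), or 0.64 without WT replicate 1 (adjusted p = 0.074). In all 10370 sites were higher and 11480 lower relative to the typical site. The count was 11907 without WT replicate 1 and 12659 without WT replicate 2. With library totals the Il1b, Ccl2 and Atp2a3 changes were 4.26, 2.82 and -0.82 in place of 2.32, 0.81 and -2.71. In all 55823 sites were then higher and 18 lower (a shift of 1.88), as the share of tags in peaks went from 6.9% and 7.5% to 28.8% and 29.2%.

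The JunB responses to LPS differed between KO and WT, with a positive difference at 1320 sites and a negative one at 1850, or 1950 and 1225 with library totals (a shift of 0.11). The count was 504 without WT replicate 1, 434 without WT replicate 2, 5204 without KO replicate 2, 1924 without WT with LPS replicate 1, 2038 without WT with LPS replicate 2, 1692 without KO with LPS replicate 1, 1687 without KO with LPS replicate 2, and 14 in a fit without precision weights. A site near Myom2 (chromosome 8, 15519764 to 15520102) differed by -3.92 ± 0.41 (adjusted p = 1.72e-10, 0.0609 without precision weights), with 13.8 tags in WT, 104 in KO, 22.7 in WT with LPS and 11.05 in KO with LPS libraries. The Ccl2 site at 81837289 on chromosome 11 differed by -0.98 ± 0.25 (adjusted p = 0.015). It was -0.62 without KO replicate 1 (adjusted p = 0.285), and did not pass without WT replicate 1 (adjusted p = 0.181) or WT replicate 2 (adjusted p = 0.0885), with a pseudocount of 0.25 (adjusted p = 0.0553) or without precision weights (adjusted p = 0.154).

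MED1 with LPS was higher at some chemokine sites in KO cells. The Ccl2 site (chromosome 11, 81847911 to 81853820) went from 105 to 210.0 tags (log2 0.99 ± 0.11, adjusted p = 3.92e-11, and 0.23 with library totals, adjusted p = 0.0584). A site near Lrpap1 (chromosome 5, 35506039 to 35512277) went from 42.0 to 208 and one beside Trem1 (chromosome 17, 48369550 to 48372219) from 16.3 to 58.05 (log2 1.76, or 1.02 with library totals), while the Spry2 promoter (chromosome 14, 106294077 to 106298505) fell from 95.5 to 22.4. The Il6 site (chromosome 5, 30339216 to 30340333) rose by 1.08 ± 0.31 (adjusted p = 0.0173), a call lost with library totals (0.35, adjusted p = 0.303). It was also lost without WT replicate 1 (adjusted p = 0.0897), WT replicate 2 (adjusted p = 0.129), KO replicate 1 (adjusted p = 0.0834) or KO replicate 2 (adjusted p = 0.0639). Of 50 chemokine sites 13 were higher (16 higher and 1 lower adjusted over the list alone; adjusted p = 9.71e-09, or 0.28 with an estimated correlation). Of 26052 sites 1301 were higher and 519 lower, with 1017 in all without WT replicate 1 and 1034 without WT replicate 2. With library totals 159 were higher and 17516 lower (a shift of -0.74), since 8.8% and 8.9% of KO tags lay in peaks against 14.6% in each WT library.

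RNA polymerase II with LPS was far higher in KO cells at LPS-induced genes. Normalised tags went from 31.95 to 3797 at Ccl5 (chromosome 11, 83333158 to 83351061), from 143 to 8184 at Acod1 (chromosome 14, 103445151 to 103462899), from 47.0 to 1643 at Lif (chromosome 11, 4166302 to 4176120), from 106 to 835.5 at Cxcl10 (chromosome 5, 92769849 to 92778984) and from 295.5 to 1382 at Ccl2 (chromosome 11, 81847586 to 81854171). They fell from 229 to 22.8 at Spry2 (chromosome 14, 106293882 to 106298656) and from 8517 to 1097 at Lyz2 (chromosome 10, 116709387 to 116735923). The region of Gps2 (chromosome 11, 69722432 to 69736910) went from 1174 to 1597 (log2 0.44 ± 0.04), by 0.24 with the sum of tags in peaks and by -1.44 with library totals. Library totals also took Lif from 5.11 to 3.25, Cxcl10 from 2.97 to 1.09 and Ccl2 from 2.22 to 0.35 (log2). They took Spry2 from -3.32 to -5.13 and Lyz2 from -2.96 to -4.83. Sites of NF-kB genes (59 of 75 higher, 60 adjusted over the list alone, adjusted p = 7.56e-25, or 0.102 with an estimated correlation) and chemokines (18 of 24 higher, 18 adjusted over the list alone, adjusted p = 4.97e-16, or 0.244 with an estimated correlation) rose, and 32 of 66 cell cycle sites fell, with 3 higher (33 and 3 adjusted over the list alone; adjusted p = 3.72e-06, or 0.209 with an estimated correlation).

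These RNA polymerase II changes ran with the LPS response more than with the RNA change of KO against WT cells with LPS. Across 9841 genes, which are not independent replicates, their Pearson r was 0.475 with the RNA response to LPS in WT cells (rho 0.38) and 0.0128 with the RNA change of KO against WT with LPS (rho -0.0424). Ccl5 RNA was lower in KO cells with LPS (20150 ± 5510 against 9631 ± 128), opposite to its RNA polymerase II. The RNA libraries were made longer after LPS than the ChIP-seq libraries. These comparisons thus cannot tell a difference in time from a disagreement between RNA and RNA polymerase II. In the WT libraries the genes that LPS induced held 0.34 more RNA polymerase II (log2) than unchanged genes of like untreated RNA, with a 95% bootstrap interval of -0.03 to 0.56, against 1.62 in the KO libraries (1.28 to 2.03). An LPS response of RNA polymerase II at these genes was thus not shown in the WT libraries, and the change between genotypes is not shown to be an effect of the knockout. Of 23081 sites 5361 were higher and 4894 lower; with library totals 641 were higher and 20842 lower (a shift of -1.80), since 46.4% and 45.0% of WT tags lay in peaks against 14.2% and 14.4% of KO tags.

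Within 100 kb of Ccl2, all 6 RNA polymerase II sites were higher in KO cells with LPS, by 1.66 to 3.81 (log2). Of 12 MED1 sites 7 were higher and 0 lower, and all 12 changes were positive, the lowest 0.14. Both patterns rest on the scaling, since library totals shift MED1 by -0.74 and RNA polymerase II by -1.80. Of 24 JunB sites 7 were higher and 2 lower, and of 16 PU.1 sites 2 were higher and 1 lower. Without LPS, 2 of 18 ATAC-seq sites were more open, 2 of 16 PU.1 sites and 1 of 24 JunB sites higher, and 0 lower in each. In WT cells LPS raised JunB at 12 of the 24 sites and lowered it at 1, and raised PU.1 at 6 of the 16 and lowered it at 1.

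**Figure D3:**
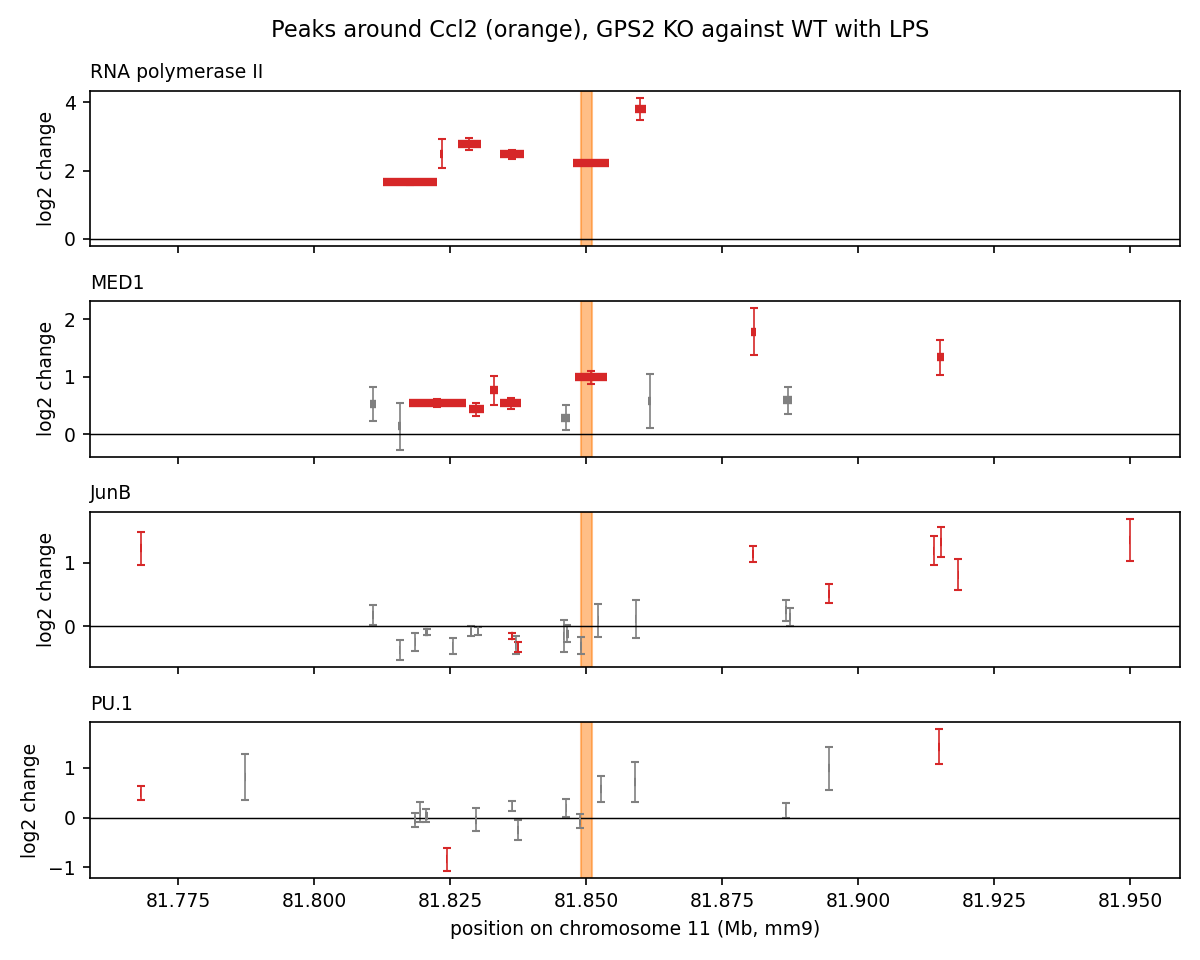
Log2 change in KO against WT cells with LPS (vertical axes) at every tested peak within 100 kb of Ccl2 (orange) on chromosome 11, mm9 (horizontal axis, Mb), for 4 ChIP-seq targets; bar widths are peak widths, whiskers are SE, and red marks adjusted p under 0.05. All 6 RNA polymerase II peaks are red and positive, as are 7 of 12 MED1 peaks.

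Changes at sites followed RNA only weakly. Open chromatin changed by 0.05 more (log2, difference of medians) at genes with more RNA in KO cells without LPS than at genes with less (2028 and 1926 genes; permutation p = 1e-05, the smallest 100000 draws can give). With LPS the difference was 0.05 for PU.1 (permutation p = 9e-05), 0.05 for JunB (permutation p = 2e-05) and 0.02 for MED1 (permutation p = 0.132). For RNA polymerase II it was -0.10 (permutation p = 1e-05). For genes whose RNA changed by at least 1 (log2) the differences were larger for open chromatin (0.13), PU.1 (0.16), JunB (0.16) and MED1 (0.23; permutation p = 1e-05 for each), while that of RNA polymerase II turned to 0.14, which did not pass (permutation p = 0.0522). At peaks within 1 kb of a transcription start the PU.1 and JunB differences were -0.01 and -0.0013, which did not pass (permutation p = 0.384 and 0.943). That of MED1 was -0.03 (permutation p = 0.0485). Farther away the differences were 0.07 for PU.1, 0.06 for JunB and 0.09 for MED1 (permutation p = 1e-05 for each). These tests are over genes, which are not independent replicates. With LPS, the RNA was also taken at a later time than the ChIP-seq. A weak relation there cannot be told from a difference in time.

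The peak sets overlapped broadly. Of 26052 MED1 sites 91.45% touched an ATAC-seq site, 80.5% a JunB site and 65.1% a PU.1 site. Of 52009 PU.1 sites 72.6% touched an ATAC-seq site and 41.8% a JunB site, and of 58810 JunB sites 67.7% touched an ATAC-seq site and 37% a PU.1 site. These shares count 1 shared base; MED1 and RNA polymerase II regions are much wider than PU.1 and JunB sites, so asking for 50% of both peaks leaves 6.53% of MED1 sites with a JunB site.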

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

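The test of a mislabelled library was chosen only after the result was seen, and the others in this part were planned or chosen before it. Within groups of 4 RNA-seq libraries, 21 of 254 values tested (of genes named in the text and of library measures) had 1 library far from the other 3, where chance gives about 13 (1 in 20 groups). Of these 21, 11 lay in WT with LPS, and in all 11 replicate 4 stood apart. Dixon's ratio, the gap to the nearest library over the whole range, was 0.958 for Gps2, 0.835 for Ccl2, 0.951 for Gpnmb, 0.893 for Scarf1, 0.866 for Gja1, 0.848 for Nfkbie, 0.837 for Tapbp, 0.849 for Saa3, 0.863 for Hdac3, 0.882 for the rank correlation of the deviation on transcript length and 0.878 for the scaling divisor. The other 10 were Csf3 (0.855) in WT; Zfp395 (1), Slc7a11 (0.925) and Cxcl16 (0.843) in KO; and Tnf (0.911), Treml2 (0.854), Cd80 (0.943), Il7r (0.84), Tbl1x (0.904) and the spread of the deviation (0.861) in KO with LPS. Zfp395 was listed at 0 in 3 of the 4 KO libraries.

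Replicate 4 of WT with LPS differed from replicates 1 to 3 by transcript length: the median deviation from the group was -0.69 (log2) for the quartile of longest transcripts and 0.64 for the quartile of shortest. The spread of its deviation was 0.713, against 0.0539 to 0.318 in the other 15 libraries. A trend on transcript length alone is argued against as the whole cause, since a spread of 0.373 stayed after each library's trend was removed, above the highest of the others (0.171). A mislabelled KO or untreated library is argued against by its Gps2 value of 496, against 420 to 424 in replicates 1 to 3 and at most 98.5 in KO with LPS, and by its Ccl2 value of 41300, against at most 95.01 in untreated WT libraries. Degraded RNA or another way of making this library stays open, untested, and no biological explanation was tested since the design names none within the group.

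The LPS response differed between KO and WT, tested as its own term, for 2436 genes in RNA, at 4303 PU.1 sites and at 3170 JunB sites. In RNA the differences were 2.49 for Pilra, 2.47 for Cd36, 2.32 for Ccnd1 and 0.98 for Rrm2. On the other side they were -3.81 for Cth, -3.755 for Trib3, -3.71 for Abca1, -3.46 for Il7r, -3.09 for Chac1, -3.01 for Saa3, -2.58 for Il1rn, -2.56 for Cd86, -1.56 for Asns, -1.36 for Nos2, -1.14 for Dusp1, -0.94 for Nfkbie, -0.77 for Ctsb and -0.57 for Gps2. For PU.1 they were -2.19 at the Txndc11 site and -1.04 at the Ccl2 site at 81824167 to 81824441. For JunB they were -3.92 at the Myom2 site and -0.98 at the Ccl2 site at 81837289 to 81837627.

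For 5 counts of RNA genes the real grouping of the libraries gave more than any other grouping tried. The other groupings mixed libraries of the real groups, so they cannot exclude a chance difference between the cultures. Of the 35 splits of 8 libraries, only 1, the real one, gave as many genes as it: 7207 for KO against WT without LPS, 3132 with LPS, 6971 for LPS in WT and 9631 for LPS in KO, where the highest of the other splits gave 0 each time. These counts come from fits of only the groups compared. For the difference of the LPS responses the real grouping gave 2436 genes and the highest of the other 99 drawn gave 987. For ATAC-seq the 10 splits are too few for a share under 0.05; the real one gave 5271 sites and the highest of the others 1.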

How the results depend on the processing

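Alternatives named as added were chosen after seeing the data; the cause of a change was not tested unless the setting itself gives it. Of the 174 genes and sites named, 165 were called; 120 of these stayed past the threshold with the same sign under every alternative run, and 164 kept their sign. With a library left out, 2254 of 2302 values stayed on their side, 43 lost and 4 gained the call and 1 changed sign uncalled; under the other alternatives 2181 of 2252 stayed, 61 lost and 5 gained it, 4 changed sign uncalled and 1 reversed. Over all 727 genes and sites of the rule, 7885 of 8234 and 8474 of 8912 stayed, and 1 and 34 reversed. Of the counts, 123 of 158 with a library left out and 154 of 202 others stayed within 1.5 times; of the list tests, 1081 of 1240 kept their call, 58 lost and 99 gained it and 2 reversed. Overlaps all moved (20 of 20) when 50% of both sites was asked. Simulated 2-fold changes were recovered least in the difference of the JunB responses, 25 of 200.

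With 1 library left out, counts ran from 3514 to 6993 for RNA without LPS, 2056 to 4620 for the RNA difference of responses, 3189 to 4087 for ATAC-seq; for PU.1 1620 to 4106 without LPS, 1777 to 4734 with LPS, 4480 to 9602 for LPS in WT and 2585 to 3710 for the difference; for JunB 1027 to 6769, 9198 to 17123, 11907 to 24714 and 434 to 5204 in the same order; and 1017 to 1585 for MED1.

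A fit of only the groups compared called 7207 genes without and 3132 with LPS. Against a log2 change of 1, 372, 362, 2117 (LPS in WT), 1768 (LPS in KO) and 133 (difference) genes passed. Library weights (added) gave 7345 without LPS and 4559 for the difference. ATAC-seq counts were 719 within 1 kb of a transcription start, 13 at the stricter threshold and 3469 with a stricter filter (added); the first and last test fewer sites. Library totals called 24352 (without LPS), 14152 (with LPS) and 31598 (LPS in WT) PU.1, 55841 JunB (LPS in WT), 17675 MED1 and 21483 RNA polymerase II sites, and turned the Gps2 region of RNA polymerase II to -1.439. Within 1 kb, where fewer sites are tested, there were 258, 143, 900 and 206 PU.1, 3311, 718, 2749 and 1966 JunB, 409 MED1 and 3580 RNA polymerase II sites; farther away 1554 (without LPS) and 1449 (difference) JunB and 6711 RNA polymerase II sites. The stricter threshold left 599, 1191, 2169 and 1448 PU.1, 1912, 3098, 9380 and 619 JunB, 267 MED1 and 4156 RNA polymerase II sites. Without precision weights (added as an alternative) there were 1932 (without LPS) and 6139 (LPS in WT) PU.1 and 16 (with LPS), 13140 (LPS in WT) and 14 (difference) JunB sites. That fit had been tried before the weighted one was chosen. A pseudocount of 0.25 or 5 (added) gave 1732 and 2059 for the JunB difference.

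Between genes with more and less RNA, the difference at sites within 1 kb changed sign. It was -0.01419 for PU.1 and -0.001284 for JunB, which did not pass (permutation p = 0.384 and 0.943), and -0.02597 for MED1 (permutation p = 0.0485). For MED1 it was 0.08988 farther than 1 kb, -2.248e-05 at the highest site of each gene, 0.2341 for RNA changes of at least 1 and 0.02308 without replicate 4 of WT with LPS (added); for RNA polymerase II it was -0.04733 farther than 1 kb and 0.1437 for RNA changes of at least 1. Of RNA list tests 20 passed with an estimated correlation, 77 with fry and 84 with its mixed test; of peak list tests 0, 72 and 212 (fry added for peaks). With library totals (added) the MED1 tests of the NF-kB and AP-1 lists turned direction, with adjusted p of 0.0835 and 0.77.

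A replicate block, with the replicate number as a term, called 3882, 4911, 8148, 7819 and 2154 genes in RNA, 5267 ATAC-seq sites, 4114, 4771, 9081 and 4423 PU.1 sites, 6341, 13014, 21813 and 3705 JunB sites, 1789 MED1 and 10405 RNA polymerase II sites, each within 1.5 times. Replicate numbers are shared across groups but did not pair the samples: the deviations of libraries with the same number correlated by -0.367 to 0.211 in RNA-seq, and 1 of 24 such pairs exceeded 0.1. Not run, though the recovered reads would have allowed it for RNA-seq and ChIP-seq, were the DESeq2 test and its calls in the comparison of sites with RNA. The count filters and scalings of ATAC-seq were not run, as its values hold no counts. Testing every transcript was moot, since no symbol was shared.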

Other observations

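The tests of the LPS response in the WT libraries of RNA polymerase II and MED1 were chosen only after the result was seen. So was the use of the promoter gap for a change of all sites alike. The interval rules for genes with more and less RNA and for PU.1 at JunB promoters were also chosen then. Away from promoters, sites gained in KO cells held the C/EBP motif more often than lost sites did (Fisher's exact test, adjusted over 15 tests). The difference was 6.69 points for ATAC-seq without LPS (20.9% against 14.2%, adjusted p = 3.44e-08), 8.39 for PU.1 with LPS (23.96% against 15.6%, adjusted p = 4.02e-11) and 4.75 for JunB with LPS (23.25% against 18.5%, adjusted p = 8.44e-12). Sites not called held the motif at 16.97% for ATAC-seq, 16.97% for PU.1 and 19.3% for JunB. Gained sites lay above and lost sites below these shares each time. Within quintiles of GC content the difference between gained and lost sites was 5.2, 9.06 and 4.78 points. Gained sites were higher in all 5 quintiles each time. The motif was searched as TTRCNNAA (R is A or G, N any base), and its share by chance was not tested. The PU.1/ETS motif was more frequent at gained PU.1 sites by 7.36 points (adjusted p = 5.39e-07). The AP-1 motif was less frequent at gained than at lost sites of PU.1 by -2.97 points (adjusted p = 0.00472) and of JunB by -10.8 points (55.5% against 66.25%, adjusted p = 4.42e-40). JunB sites not called held it at 55.1%, close to the gained sites, so the JunB gap lay in the lost sites. For PU.1, gained (9.19%) and lost (12.2%) sites both lay below sites not called (15.5%). Within quintiles of GC content the differences were -3.28 and -10.7 points, with gained sites higher in 2 and 0 of 5 quintiles.

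The other motif differences did not pass. They were 2.2 points for AP-1 (adjusted p = 0.1), -1.48 for PU.1/ETS (adjusted p = 0.0948), -0.562 for NF-kB (adjusted p = 0.317) and -0.0126 for IRF (adjusted p = 1) at ATAC-seq sites. At PU.1 sites they were 1.14 for NF-kB (adjusted p = 0.0691) and -0.178 for IRF (adjusted p = 0.866). At JunB sites they were -0.631 for PU.1/ETS, 0.414 for NF-kB and 0.379 for IRF (adjusted p = 0.181 each).

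MED1 moved with JunB in KO cells with LPS. At MED1 sites that overlap JunB sites called higher the median change was 0.49, and at those that overlap JunB sites called lower it was -0.17, a difference of 0.6597 (1973 and 4834 sites; permutation p = 1e-05, the smallest 100000 permutations can give). For RNA polymerase II the difference was 0.2555 (899 and 2755 sites; permutation p = 1e-05) and for PU.1 0.74. RNA polymerase II did not fall where JunB fell: its median change was -0.002191 at lost JunB sites, above the -0.1227 at JunB sites not called. Each stood in 10 of 10 deciles of site height. Sites are not independent replicates, and the libraries of a condition are 1 sample.

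JunB rose at promoters in KO cells without LPS, and a hypothesis is that part of these gains may be background tags in place of binding. Of 2441 gained promoter sites 5.408% held the AP-1 motif (95% interval 4.58 to 6.38), against 31.3% of promoter sites not called (30.0 to 32.5), as this explanation requires. The GC content of the gained sites was also higher, 66.5% against 56.0%, which the motif test did not match. A shift of promoter signal that other antibodies share did not reach the size asked for at PU.1 peaks. PU.1 changed by 0.0347 more at gained JunB promoters than at others (permutation p = 0.0235, 95% interval -0.00177 to 0.0663), under the 0.1 that this explanation asked for. Untreated PU.1 libraries held 17.2% to 25.2% of tags in peaks and untreated JunB libraries 5.8% to 7.5%. A shared background shift may thus be diluted at PU.1 peaks and is not excluded. An effect of the knockout on JunB itself stays open.

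RNA polymerase II with LPS was higher at LPS-induced genes in KO than in WT libraries, and lower at promoters than elsewhere. WT libraries without an LPS response are a candidate explanation for the former. Induced genes lay 0.336 (log2) above unchanged ones in WT (95% interval -0.03 to 0.56, 9 of 10 deciles) and 1.62 above in KO. MED1 libraries of the same WT condition stood at 1.45 (1.06 to 1.68), so this test gave no sign of a missing response there. No untreated library of either target entered the test, so a level present before LPS cannot be told from a response. The gap between promoters and other sites was -0.351 over all sites. At matched height in WT it was -0.207 (95% interval -0.235 to -0.177, lower in 10 of 10 deciles), beyond the 0.1 asked for. Sites were matched on WT height but not on width, with which background tags grow. The test thus cannot decide whether lower enrichment of the KO libraries is the whole cause of the gap. The part that goes with height also stays open. A change of all sites alike would leave no such gap. That gap is the pattern to be explained, so it is no separate test of this explanation. The difference between genes with more and with less RNA (-0.1036, 95% interval -0.142 to -0.0555) did not decide the question, lying on both sides of the 0.1 asked for. A biological effect of the knockout stays open, and cannot be separated from the state of the WT libraries with 1 sample per condition.

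The authors' calls and those made here never went in opposite directions: 0 genes or sites called by both differed in sign in the 12 comparisons. Their log2 changes correlated across genes or sites with Pearson r of 0.98 to 0.99 for RNA, 0.963 to 0.996 for ChIP-seq and 0.692 for ATAC-seq, where genes and sites are not independent replicates. The counts differed: the authors called 19 JunB sites without LPS and 149 PU.1 sites without LPS, against 5159 and 4087 here, and, of the 11791 genes tested here, 5911 without LPS against 4180 here.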
